A study of Mus musculus with 168 samples.

How the data were processed

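Male C57BL/6 mice aged 6 weeks received a JAK inhibitor or its vehicle by gavage, and immune cells sorted from the spleen or the peritoneal cavity were profiled on Affymetrix Mouse Gene 1.0 ST arrays. The inhibitors block Janus kinases, which carry signals from interferon and interleukin receptors to STAT transcription factors. Each of the 168 arrays holds RNA of 1 cell type from 1 tissue. Compounds are named only by their codes in the labels, and the labels used here give no dose.

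The deposited values are intensity per probe set, which the authors made by RMA with Affymetrix Power Tools per the labels. The versions, the annotation release and the set of arrays normalized together are not given in the sources used here. The values were taken as linear and not as log2, because array medians ran from 119.5 to 142.3 (median 128.8) and array maxima from 14904 to 22294. The lowest value was 5.11, so log2 was taken without a pseudocount. All fold changes and list means below are on that log2 scale. Arrays have no read depth, and their number limits the precision. The 168 arrays were checked for copies, with 0 identical pairs and a highest correlation between 2 arrays of 0.9972.

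Of the 24922 probe sets in the table, 21425 carried 1 gene symbol. The 1399 probe sets with several symbols and the 2098 without an annotation line were left out. Symbols were matched to the RefSeq gene table of GRCm38 by gene identifier, which found 21347 of them and changed 0. For each of 19752 genes the probe set with the highest mean over all arrays was kept. A gene was tested in a tissue and cell type if its value was above the median of its array in at least 3 of those arrays. The arrays come with no positions of their probe sets, so no coordinates are given.

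Samples were grouped by tissue, cell type, compound and schedule from the labels. The experiment is the first part of each title (J2, J3, J6, J8, J12, J23 or J25). A title number shared within an experiment was taken as 1 animal, giving 80 animals. The labels do not otherwise state which arrays share an animal, so p-values measure the spread between these samples. Replicate numbers within a group follow only the order of the deposited arrays. The plain vehicle was 0.5% MC (methylcellulose), and 0.5% MC at pH 3 was kept as a group of its own.

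Each tissue and cell type was fitted on its own with limma 3.58.1 in R 4.3.3. The model held group and experiment as fixed effects, and moderated tests (two-sided) used the empirical Bayes spread of all arrays of the cell type. Benjamini-Hochberg adjustment ran over the genes tested in each contrast, with a threshold of adjusted p 0.05. Contrasts against vehicle weighted each compound by its number of arrays. Groups with 1 array were tested with the spread of the other groups, so that array is assumed to vary like them. Arrays taken 4 h after the last of 3 treatments had no vehicle of the same schedule and were set against the plain vehicle of 14 or 15 treatments. Differences of the prolonged effect between cell types were tested with a moderated F test that allowed for a correlation between arrays of 1 animal.

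The design, the contrasts and 29 gene lists were fixed before the data were examined. Lists were tested with fry of limma, which asks whether the genes of a list move on balance one way. P-values were adjusted over the lists of a family of contrasts. A family held the same kind of contrast in all spleen cell types, all single compounds against vehicle, all pairs of compounds, or both contrasts of the vehicles. Each peritoneal contrast of pooled inhibitors was a family alone, so families differed much in size. The size of a list change is the mean log2 difference over its tested members, with the standard error of the same contrast on each array's list mean. Within lists, members past the threshold were counted over all genes tested and adjusted over the list alone. Named genes followed a rule: per contrast against vehicle the 8 largest rises and 8 largest falls past the threshold, and up to 4 members of each list with the largest moderated statistic. Jak1, Jak2, Jak3, Tyk2, Irf7, Socs1, Socs2, Socs3, Cish and Pim1 were always included where tested, and 1 further gene of the rule is not reported here. Where no gene passed, the 2 highest and 2 lowest genes by moderated statistic were named. Genes of contrasts between schedules or compounds lie outside the rule and were chosen after their values were seen.

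The pipeline was tested on simulated data with the same arrays and groups. A change of 1 on the log2 scale was recovered in 100% of genes in spleen MF, 98.5% in DC, 88.1% in NK, 98.5% in T4 and 82.1% in GN for the prolonged contrast, and in 100% in peritoneal MF early. For a change of 0.5 the shares were 88.1%, 65.7%, 41.8%, 80.6%, 23.9% and 86.6%. Between cell types, 100% of 200 simulated differences of 2 were recovered. In the simulation each gene varied independently around its mean, without differences between experiments, correlated genes or outlying arrays. The shares are therefore not the power in the real arrays.

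Alternatives planned in advance were no experiment term, the experiment as a random block, no expression filter, quantile normalization within the cell type, array quality weights, both vehicles as 1 control group, the pH 3 vehicle for SB00526226, only experiments holding both vehicle and inhibitors, no arrays of 28 treatments, vehicle of 14 treatments alone, arrays at 3 h alone, camera with an estimated correlation in place of fry, and leaving out each array in turn. Added after seeing the data were the fits without 12 arrays standing apart, with T4 of some experiments alone and with experiment J2 alone, and leaving out arrays for the contrasts between schedules. An array stood apart if its median correlation with its cell type lay below the lower quartile by over 3 interquartile ranges, or if a marker list of other cells lay as far above the upper quartile and over 0.5 above the median. Other splits of the same arrays were drawn for each contrast with at least 3 arrays per group. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.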

Results

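The series asks which transcripts of sorted mouse immune cells change when JAK kinases are blocked in the living animal. Spleen arrays cover 5 cell types: MF (sorted as F4/80+ macrophages, 33 arrays), DC (FLT3+ dendritic cells, 20 arrays), NK (NK1.1+ natural killer cells, 27 arrays), T4 (CD4+ T cells, 39 arrays) and GN (Ly6G+ granulocytes, 16 arrays). Peritoneal MF make up the other 33 arrays, 168 in all from 80 animals. The compounds were SB00513404 on 20 arrays, SB00526221 on 32, SB00526222 on 43, SB00526226 on 18 and SB00526228 on 9. The plain vehicle was on 39 arrays and the vehicle at pH 3 on 7. Prolonged spleen groups had 14, 15 or 28 treatments and were taken 14 to 18 h after the last treatment. A second spleen schedule was taken 4 h after the last of 3 treatments. In T4 of J25 there were also arrays after a single treatment. These were 1 of SB00513404 and 1 of vehicle at 3 h, and 2 of SB00513404 and 1 of SB00526222 at 18 h. Peritoneal groups were taken early after a single treatment (1.5 to 6 h), late after it (18 to 28 h) or 18 h after the last of 14 treatments. Genes tested numbered 10978 in spleen MF, 10831 in DC, 11008 in NK, 11246 in T4, 11089 in GN and 10810 in peritoneal MF.

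Each sorted population carried its own markers. Adgre1, which encodes F4/80, averaged 12.72 ± 0.12 (SD, n = 33) in arrays labelled spleen MF and 12.7 ± 0.14 (SD, n = 33) in peritoneal MF. Flt3, the cytokine receptor used to sort dendritic cells, averaged 11.74 ± 0.27 (SD, n = 20) in DC and at most 6.80 on average elsewhere. The activating receptor gene Ncr1 reached 13.38 ± 0.14 (SD, n = 27) in NK. Cd3e, a chain of the T cell receptor complex, averaged 12.56 ± 0.16 (SD, n = 39) in T4, and Ly6g averaged 13.03 ± 0.33 (SD, n = 16) in GN. Gata6, the transcription factor that sets the identity of large peritoneal macrophages, was at 11.14 ± 0.27 in spleen MF and 11.17 ± 0.23 in peritoneal MF, and between 6.18 and 7.10 in the other cell types. Vcam1, an adhesion molecule of red pulp macrophages, was at 5.99 ± 0.16 in spleen MF and 8.03 ± 0.48 in DC. The arrays labelled spleen MF therefore carried peritoneal macrophage markers, and the tissue label is used below as given.

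**Figure D1:**
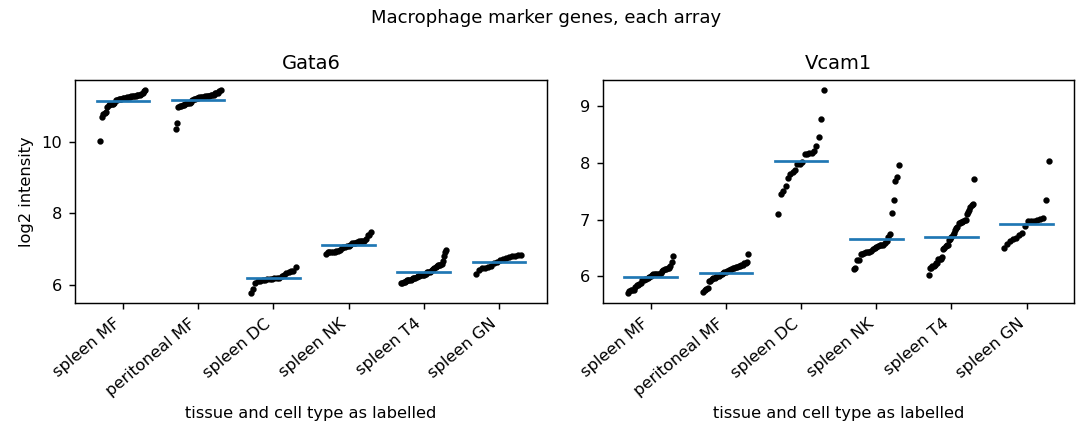
Gata6 and Vcam1 per array (points sorted by value, log2 intensity on the vertical axis) by tissue and cell type on the horizontal axis, with means as lines. Gata6 averaged 11.14 in arrays labelled spleen MF and 11.17 in peritoneal MF, against 6.18 in DC.

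In peritoneal macrophages the question was how fast a single dose lowers genes that interferon receptors keep on through JAK1 and TYK2. Genes of the antiviral program fell within hours. Rtp4, which encodes an interferon-induced receptor transporter (probe set 10434778), averaged 8.11 ± 0.58 (SD, n = 12) with inhibitor and 9.74 ± 0.66 (SD, n = 6) with vehicle. This was 3.22-fold lower, a change of -1.69 on the log2 scale (SE 0.27, adjusted p = 0.0051, lower in 11 of 12 arrays). Oasl2 and Oas2, of the oligoadenylate synthetase family that senses viral RNA, fell by 1.202 and 1.08, each lower in 12 of 12 arrays. Irf9, a transcription factor of the type I interferon response, fell by 0.55 (adjusted p = 0.0455, lower in 10 of 12 arrays). Slfn5, Slfn8, Ifit1, Xaf1, Gm12250 and Ddx58, the viral RNA sensor also called RIG-I, completed the set of 10 genes lower and 0 higher. Irf7, the factor that amplifies interferon production, lay 0.69 lower without passing (adjusted p = 0.46, lower in 8 of 12 arrays).

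The 10 genes passed among 380 at an unadjusted p under 0.05 in the comparison of 12 inhibitor and 6 vehicle arrays. The interferon-stimulated list averaged -0.52 (SE 0.12, adjusted p = 0.00747 by fry and 0.00302 with an estimated correlation), with 8 of 34 members lower over all genes and 25 adjusted over the list alone. Within experiments the list differed by -0.78 in J12, -0.05 in J23 and -0.36 in J25, so the size rested mainly on J12. Rtp4 differed by -2.16, -0.84 and -1.45 in the same order, whereas Irf9 was +0.10 in J23. In J12, vehicle replicate 1 had a list mean of 9.865, against 8.94 for the other early vehicle arrays. The J12 vehicle arrays had an SD of 0.5. In J23 the only vehicle array was taken at 6 h and the inhibitor arrays at 1.5 to 6 h, so hours were not matched. The labels also give other sort markers for J12 than for J23 and J25. Experiment, hour and sort were therefore not separated. Leaving out vehicle replicate 1, 2 or 5 left 2 genes, and leaving out vehicle replicate 4 gave 26. Of 100 splits of the same arrays, 5 called as many genes, the real one included. The list stayed past its threshold without any 1 of the 18 arrays, with means of -0.62 to -0.36.

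**Figure D2:**
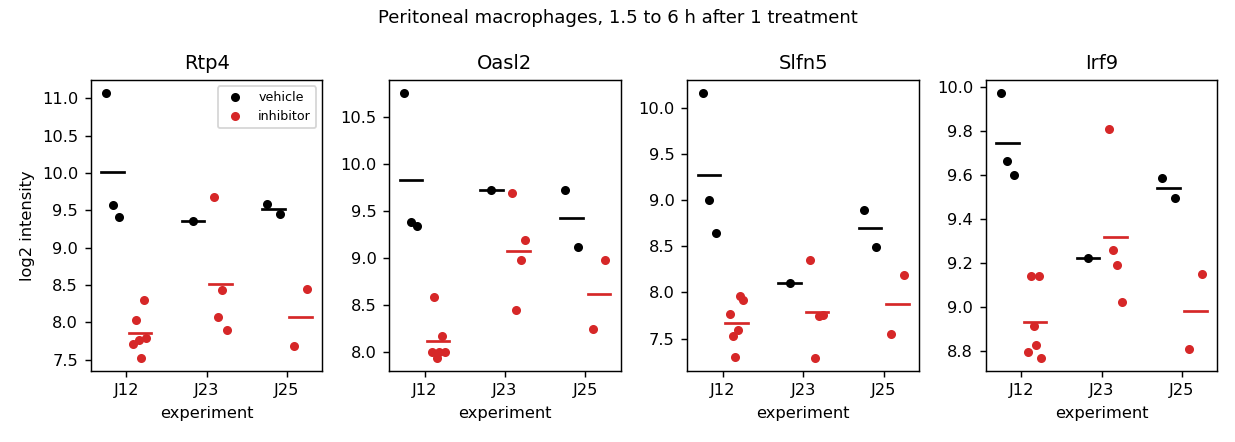
Rtp4, Oasl2, Slfn5 and Irf9 per array (points, log2 intensity on the vertical axis) in peritoneal MF 1.5 to 6 h after 1 treatment, by experiment on the horizontal axis, with vehicle in black, inhibitors in red and lines at the means. Over all experiments Rtp4 averaged 8.11 with inhibitor and 9.74 with vehicle.

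At 18 to 28 h after the single treatment Rtp4 lay 0.66 below vehicle (adjusted p = 0.919, lower in 7 of 8 arrays), and Isg20, an interferon-induced exonuclease, was at -0.23. The interferon-stimulated list averaged -0.17 (SE 0.16, adjusted p = 0.936). After 14 treatments, taken 18 h after the last, Ifi27l2a, an interferon-induced gene of the mitochondrial and nuclear membrane, was at -0.82 and the list at -0.09 (SE 0.18, adjusted p = 0.941). Lower there without passing were the mitotic kinase gene Bub1 at -1.197, the spindle motor gene Kif11 at -1.13 and the thymidylate synthase gene Tyms at -0.81 (adjusted p = 0.976). The limma test called 0 genes late (284 at an unadjusted p under 0.05, 8 against 3 arrays) and 0 after 14 treatments (520, 4 against 3 arrays). Both used the same 3 vehicle arrays, of which 1 (J23) had 1 vehicle treatment and 2 (J25) had 14, so the control of the single dose was mixed in number of treatments. With that control, the early effect was not shown to differ from the late one: limma called 0 genes (187 at an unadjusted p under 0.05).

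In spleen MF after prolonged treatment the question was whether interferon-dependent transcripts stay lower over days of dosing. Ifi27l2a (probe set 10402347) averaged 7.41 ± 0.59 (SD, n = 18) with inhibitor and 8.49 ± 0.56 (SD, n = 8) with vehicle. It fell by 0.95 (SE 0.15, adjusted p = 0.00885, lower in 16 of 18 arrays), the only gene past the threshold among 379 at an unadjusted p under 0.05. Rtp4 and Oasl2 lay 0.72 and 0.49 lower without passing (adjusted p = 0.164 for each), and so did the mitotic kinase gene Plk1 at -0.52 (adjusted p = 0.164, lower in 15 of 18 arrays) and the tubulin regulator gene Stmn1 at -0.59. Within experiments, Ifi27l2a differed by -0.21 in J2, -0.63 in J3, -1.45 in J6 and -1.34 in J8. The interferon-stimulated list averaged -0.17 (SE 0.05, adjusted p = 0.335), with 1 of 33 members lower over all genes and 5 adjusted over the list alone. The call was lost without the experiment term, 6 of 100 splits of the arrays called as many genes, and without vehicle replicate 7 the count was 41.

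SB00526221 gave the most called genes of the prolonged compounds in these macrophages. H2-Aa, an MHC class II chain, fell by 1.11 (SE 0.21, adjusted p = 0.03) and Cd74, the invariant chain that guides class II molecules, by 0.94 (SE 0.20, adjusted p = 0.0429), both lower in 6 of 6 arrays. Ifi27l2a fell by 1.40, Rtp4 by 1.16 and Oasl2 by 0.73, and Cdkn3, E2f8, Knl1, Plk1, Kif2c and the thymidine kinase gene Tk1 were also called. None of the lists of these genes passed as a list: the MHC class II mean was -0.57 (SE 0.15, adjusted p = 0.204), the interferon-stimulated mean -0.30 (SE 0.07, adjusted p = 0.125) and the cell cycle mean -0.60 (SE 0.16, adjusted p = 0.197). These values by fry were adjusted over the lists of all single-compound contrasts, and unadjusted they were 0.00263, 0.000763 and 0.00189. Other lists were also lower without passing: NF-kB at -0.26 (unadjusted p = 0.000361), immediate early at -0.24 (0.00234), STAT6 at -0.25 (0.00365) and STAT3 at -0.20 (0.0064). No list that was higher had an unadjusted p as low. All 18 called genes were lower in the 6 arrays against 8 of vehicle, among 652 at an unadjusted p under 0.05. The count was unstable: it was 1 without vehicle replicate 4, 5 or 8 or without inhibitor replicate 4 or 6, and 66 without vehicle replicate 7. It was 3 with the random block or without the experiment term and 1 after quantile normalization. With SB00526222, Ifi27l2a alone passed, at -1.11 (SE 0.19, adjusted p = 0.0257, lower in 7 of 7 arrays). That call was lost with the random block, without the experiment term, without the arrays standing apart and in 9 of the 15 fits that left out 1 array. SB00526226 gave 0 genes by limma (243 at an unadjusted p under 0.05) and SB00526228, on 1 array, 0 (557).

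Taken 4 h after the last of 3 treatments, spleen MF differed from vehicle in Nr1d1 (probe set 10390691) and Nr1d2, which encode REV-ERB repressors of the circadian clock. Nr1d1 averaged 10.06 ± 0.605 (SD, n = 4) against 7.93 ± 0.40 (SD, n = 8) in vehicle, a rise of 2.291 (SE 0.36, adjusted p = 0.00589, higher in 4 of 4 arrays), and Nr1d2 rose by 1.36 (SE 0.20, adjusted p = 0.00294, higher in 4 of 4 arrays). Against the single vehicle array of J2 the differences were 1.80 and 1.09. The circadian clock list did not pass (mean 0.36, SE 0.07, adjusted p = 0.0719, 2 of 12 members higher over all genes, and 3 higher and 1 lower adjusted over the list alone). Of its genes not passing, Per2, a repressor within the clock loop, lay at -0.54 and Tef, a clock output factor, at +0.30. Oasl2 at -0.73 (adjusted p = 0.436) was lower without passing, as was Rtp4 at -0.97 (adjusted p = 0.529). These were 2 of 852 genes at an unadjusted p under 0.05, and 0 passed without the SB00526221 array. The vehicle was taken 14 to 17 h after its last treatment, so hour of harvest and inhibitor were not separated.

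In NK cells the question was what blocking the receptors of interleukin-15 and interleukin-2, which signal through JAK1, JAK3 and STAT5, does to cells that need them to survive. At 4 h after the last of 3 treatments, Gzmb, which encodes the cytotoxic protease granzyme B (probe set 10420308), averaged 10.79 ± 0.45 (SD, n = 5) against 11.93 ± 0.31 (SD, n = 3) in vehicle. It was 2.04-fold lower, a change of -1.03 (SE 0.13, adjusted p = 0.00049, lower in 5 of 5 arrays). Bcl2, the survival gene that interleukin-15 maintains, fell by 1.41 (SE 0.25, adjusted p = 0.0176) and Socs2, a feedback inhibitor induced by STAT5, by 1.43 (SE 0.23, adjusted p = 0.0127). Ifit1, an interferon-induced RNA-binding protein, fell by 1.63, and Clnk, an adaptor of immune receptors, by 1.04. Dusp2, a phosphatase that acts on MAP kinases, rose by 1.59 (SE 0.31, adjusted p = 0.0345), and the probe set annotated to the microRNA gene Mir142 rose by 2.60 (SE 0.45, adjusted p = 0.0146). Not every STAT5 target moved: Cish, another feedback inhibitor, was at -0.26 (adjusted p = 0.667) and Pim1, a survival kinase, at +0.43 (adjusted p = 0.539).

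Together 9 genes fell and 4 rose among 1199 at an unadjusted p under 0.05, with each in the same direction in 5 of 5 arrays. The vehicle had 14 or 15 treatments and was taken 14 to 15 h after the last. Hour of harvest and number of treatments were therefore not separated from inhibitor. All 5 inhibitor arrays and 2 of the 3 vehicle arrays belonged to J2, where the differences were -0.97 for Gzmb, -1.46 for Socs2, -1.47 for Bcl2 and 2.86 for Mir142. Only 1 gene passed without vehicle replicate 1 and 4 without the experiment term, while 132 passed without the arrays standing apart and 368 with array weights. The list of STAT5 targets averaged -0.26 (SE 0.11, adjusted p = 0.3), with 3 of 18 members lower over all genes, and 5 lower and 1 higher adjusted over the list alone. Granzyme B also fell with SB00526226 alone (-1.36, adjusted p = 0.000131, 2 arrays), and SB00526221, on 2 arrays, gave Socs2 at -1.78 and Bcl2 at -1.59. The single SB00526222 array had Gzmb at -1.34. With SB00526221 Gzmb was not called, and its arrays stood at 11.24 and 11.32 against 11.84 and 11.68 in the vehicle arrays of J2.

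**Figure D3:**
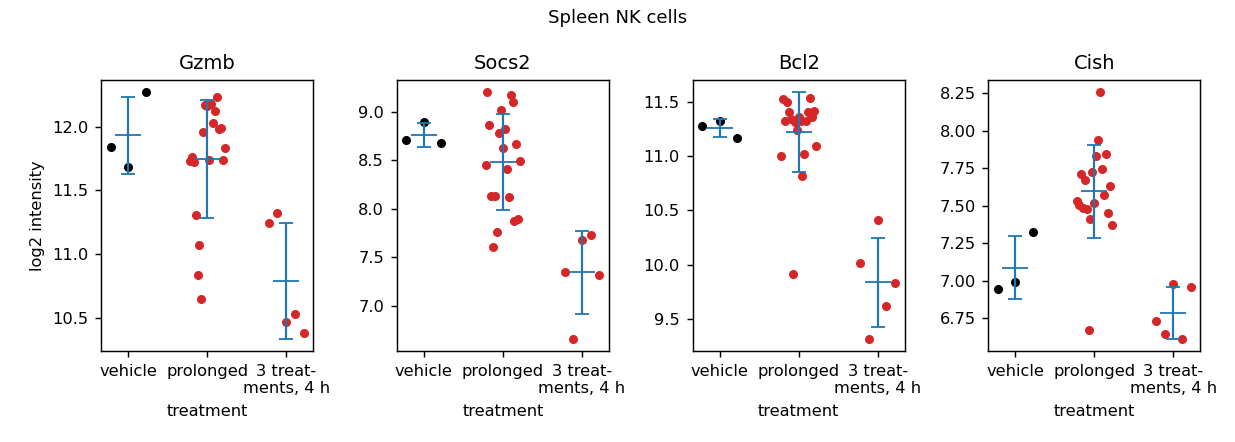
Gzmb, Socs2, Bcl2 and Cish per array (points, log2 intensity on the vertical axis) in spleen NK cells by schedule on the horizontal axis, with vehicle in black, inhibitors in red and bars at the mean ± SD. Gzmb averaged 10.79 at 4 h after 3 treatments and 11.93 with vehicle.

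In NK cells taken 14 to 17 h after the last of prolonged treatments, Ifit1 and Oasl2 lay at -0.92 and -0.61 (adjusted p = 0.998, lower in 9 of 9 arrays that had a vehicle array in their experiment), and Klrg1, a receptor of mature NK cells, at -0.86 (lower in 8 of 9 arrays). Cish was at +0.43 and Pim1 at +0.53. The limma test called 0 genes among 420 at an unadjusted p under 0.05, with 19 inhibitor arrays against 3 of vehicle. SB00526228 gave 5 lower genes on 3 arrays: Cmklr1, the chemerin receptor that guides NK cells, fell by 1.33 (SE 0.17, adjusted p = 0.000439), Ly6a2 by 1.43, F2rl2 by 1.63, Entpd1, an ectonucleotidase also called CD39, by 0.99 and Gzmb by 0.96, all lower in 3 of 3 arrays. This compound had prolonged NK arrays only in J2, and the count was 1 without vehicle replicate 1.

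The 4 h and prolonged schedules differed most in NK cells. Lower at 4 h were Myc, the growth regulator, at -0.94 (adjusted p = 0.0422), Srm, which makes the polyamine spermidine, at -1.70 (SE 0.26, adjusted p = 0.00311), the amino acid transporter gene Slc7a5 at -1.05, the cyclin gene Ccnd2 at -0.86 and Cdk6 at -1.07. Higher at 4 h were Tsc22d3, which glucocorticoids induce and which encodes GILZ, at 1.12 (adjusted p = 0.00429), Klrg1 at 1.23, the integrin gene Itgam at 0.95, Btg2 and Txnip. These genes were chosen after their values were seen, and each differed the same way in 5 of 5 arrays. In all, 97 genes passed, 28 higher and 69 lower, among 1111 at an unadjusted p under 0.05 (5 against 16 arrays). All 5 arrays at 4 h came from J2, which held only 2 prolonged arrays of SB00526221 and 1 each of SB00526222 and SB00526226. With experiments fitted, the contrast rested mainly on these prolonged arrays, and each 5 of 5 above was counted against their mean. The list of STAT5 targets averaged -0.45 (SE 0.09, adjusted p = 0.0369 by fry and adjusted p = 0.176 with an estimated correlation, 5 of 18 members lower over all genes and 9 adjusted over the list alone). The glucocorticoid-induced list averaged 0.45 (SE 0.11, adjusted p = 0.0397 by fry and adjusted p = 0.176 with an estimated correlation, 2 of 8 members higher over all genes and 3 adjusted over the list alone). Neither passed in J2 alone (adjusted p = 0.196 and 0.0813) or without the expression filter (0.0573 and 0.0952). Treatments and hours changed together between these groups, and the count ran from 37 without SB00526226 prolonged replicate 1 to 160 without the SB00526222 array at 4 h. Of the 16 prolonged arrays 4 stood apart, 2 of them with splenic macrophage markers at 7.64 (SB00526222 replicate 3) and 7.41 (SB00526221 replicate 6) against a median of 6.379, and the count was 162 without these 4, 892 without the experiment term and 18 in J2 alone.

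The same contrast of schedules gave 9 genes in spleen MF, 7 higher and 2 lower, among 840 at an unadjusted p under 0.05. Again all 4 h arrays came from J2, which held 1 prolonged array each of SB00526221 and SB00526222 and 2 of SB00526226. Nr1d1 and Nr1d2 were 4.53-fold and 2.42-fold higher at 4 h, and Prc1, Cenpa and Cdc25b, which act in cell division, rose by 1.09, 0.75 and 0.57, each higher in 4 of 4 arrays. Cxcl13, a chemokine that attracts B cells, fell by 0.59. After quantile normalization within the cell type, 10 genes were higher and 5 lower. T4 gave 1 gene (Mir142, 2.38, adjusted p = 0.000365, among 456 at an unadjusted p under 0.05). DC and GN gave 0 by limma, with 267 and 557 at an unadjusted p under 0.05. These genes were chosen after their values were seen.

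In CD4+ T cells the question was whether cells that depend on interleukin-7 and interferon through JAK1 change under the compounds. After prolonged treatment Rtp4, Oasl2 and Xaf1, an apoptosis regulator induced by interferon, lay at -0.39, -0.45 and -0.32 (adjusted p = 0.974, lower in 17, 17 and 18 of 19 arrays). None of these passed: limma called 0 genes (402 at an unadjusted p under 0.05, 19 against 7 arrays), and 5 of 37 members of the interferon-stimulated list passed adjusted over the list alone (mean -0.11, SE 0.06, adjusted p = 0.598). The pooled contrast spans experiments that differed in cell markers, with Klrb1c at 9.58 in J3, J6 and J8 and 5.41 in J2 and J25. The arrays at 4 h after 3 treatments were set against vehicle taken 14 to 18 h after its last treatment. Hour and inhibitor were not separated in that comparison. In these arrays Rsad2, the antiviral enzyme viperin, lay at -0.98 (adjusted p = 0.125) and Bcl2 at -0.58 (adjusted p = 0.563). Mir142 alone passed there, with a rise of 2.33 (SE 0.34, adjusted p = 0.00228, higher in 5 of 5 arrays; 2.38 within J2) among 219 genes at an unadjusted p under 0.05. It was lost with the random block (adjusted p = 0.358) and without vehicle replicate 1, and 14 of 100 splits of the arrays called as many genes. With SB00526221 at 4 h, on 2 arrays, the chemokine receptor gene Cxcr4 rose by 1.73 (adjusted p = 0.00185), the heat shock gene Hsph1 by 1.42 and Rgs2, a brake on G protein signals, by 1.25, while Rtp4 fell by 1.14 (adjusted p = 0.0293). That contrast called 15 genes higher and 1 lower, and the heat shock list averaged 0.65 (SE 0.13, adjusted p = 0.014 by fry and adjusted p = 0.0898 with an estimated correlation, 1 of 8 members over all genes and 5 adjusted over the list alone). Of these 2 arrays, replicate 2 carried peritoneal macrophage markers at 8.396 against a T4 median of 6.538. SB00526228 was on 1 prolonged T4 array with neutrophil markers at 9.76 against a median of 5.81, so its 190 called genes are not described further.

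Dendritic cells both make and respond to interferon. With SB00526221 after prolonged treatment, Oasl2 fell by 0.97 (SE 0.15, adjusted p = 0.036, lower in 5 of 5 arrays), the only gene called among 596 at an unadjusted p under 0.05. No gene was called with the random block, without the experiment term, or without vehicle replicate 1, 3 or 5 or inhibitor replicate 1, 3 or 5. Over all compounds, Oasl2 lay at -0.56 (lower in 11 of 12 arrays), Rtp4 at -0.55 and Zbp1, a sensor of Z-form nucleic acid, at -0.43 (each lower in 12 of 12 arrays), without passing (adjusted p = 0.979). At 4 h after 3 treatments the vehicle was again that of the prolonged schedule, so hour and inhibitor were not separated. Ifit1 lay at -1.04 in that comparison, Rsad2 at -0.86 and Isg20 at -0.77, each lower in 2 of 2 arrays (adjusted p = 0.808). A list of splenic macrophage markers averaged 0.92 higher there (SE 0.17, adjusted p = 0.0263 by fry and 0.039 with an estimated correlation), with 0 of 11 members past the threshold over all genes and 9 adjusted over the list alone. In J2 alone it did not pass (adjusted p = 0.17), nor in 4 of the 8 fits that left out 1 array. Its members Slc40a1, which exports iron, and Vcam1 lay 1.61 and 1.40 higher (adjusted p = 0.75 and 0.222). The limma test called 0 genes after prolonged treatment (187 at an unadjusted p under 0.05, 12 against 6 arrays) and 0 at 4 h (571, 2 against 6 arrays).

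In granulocytes at 4 h after 3 treatments the interferon-stimulated list did not pass, and 5 genes fell. Ifit3 and Ifit3b, near-identical genes whose probe sets were not assumed to separate them, changed by -2.02 and -2.124, Rsad2 by -1.73 (SE 0.26), Slfn5 by -1.57 and Slfn8 by -1.38 (adjusted p = 0.0394 for each, lower in 4 of 4 arrays). These were the 5 genes called among 685 at an unadjusted p under 0.05. Here too the vehicle was that of the prolonged schedule, so hour and inhibitor were not separated. J2 held the 4 inhibitor arrays and 1 of the 5 vehicle arrays, so with experiments fitted each difference rests on that 1 vehicle array and the others add only to the spread. Without SB00526221 replicate 1, SB00526222 replicate 2 or vehicle replicate 3, or after quantile normalization or without the expression filter, 0 genes passed. The list averaged -0.65 (SE 0.17, adjusted p = 0.177), with 3 of 36 members lower over all genes, and 17 lower and 1 higher adjusted over the list alone. Socs3, the feedback inhibitor of G-CSF and interleukin-6 signals, was at +1.34 without passing (adjusted p = 0.793). After prolonged treatment the granule protein genes Camp, which encodes cathelicidin, and Ltf, which encodes lactoferrin, rose by 2.40 (SE 0.26, adjusted p = 0.00365) and 2.115 (SE 0.25, adjusted p = 0.00391), and Chil3, also made in granulocyte precursors, rose 4.32-fold (SE 0.29 on the log2 scale, adjusted p = 0.0147), each higher in 5 of 6 arrays. Each experiment held another compound, and compound and experiment were not separated: Camp differed by +1.19 with SB00526228 in J2 (2 arrays against 1), +4.27 with SB00526222 in J3 (3 against 1) and -0.77 with SB00526221 in J6 (1 against 3). These 3 genes were called among 926 at an unadjusted p under 0.05, and 0 were with the random block, without the experiment term, or without SB00526222 replicate 1 or 3.

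Across cell types, the interferon-stimulated list lay below vehicle in each contrast of pooled inhibitors. Its prolonged mean was -0.17 in spleen MF, -0.19 in DC, -0.24 in NK, -0.11 in T4 and -0.15 in GN, and at 4 h after 3 treatments it was -0.20, -0.18, -0.43, -0.32 and -0.65 in the same order. These contrasts were not independent of each other. The prolonged and 4 h contrasts of a cell type used the same vehicle arrays, and many spleen arrays of different cell types came from the same animals. The late peritoneal contrast and the one after repeated treatments also shared their vehicle arrays. The common sign therefore cannot be counted as separate results, and it was not tested as such. Only the early peritoneal mean passed by fry. Its adjustment ran over the lists of that contrast alone, while each spleen schedule was adjusted over all spleen cell types together. A spleen mean thus generally needed a smaller unadjusted p to pass. With an estimated correlation T4 at 4 h also passed (adjusted p = 0.039). Within experiments the prolonged mean was +0.05 in J2 and -0.46 in J6 for spleen MF, and the compounds also differed between these experiments. In T4 it was -0.14 in J25, -0.27 in J3, -0.28 in J6 and -0.12 in J8, and the +0.07 of J2 included the SB00526228 array with neutrophil markers (9.265), while the other 3 stood at 8.621, 8.735 and 8.88 against 8.807 with vehicle. In GN, where experiment and compound coincide, it was +0.31 with SB00526228 in J2 (adjusted p = 0.767), -0.24 with SB00526222 in J3 and -0.80 with SB00526221 in J6 (1 array). In DC it was -0.19 in J2, -0.24 in J3 and -0.22 in J6, and in NK -0.27 in J2 and -0.20 in J6. A test of whether the prolonged effect of SB00526221 and SB00526222 differed between MF, DC, NK and T4 called 0 of 13182 genes by limma (257 at an unadjusted p under 0.05). The nearest, Ifi27l2a, had effects of -1.25 in MF, -0.46 in DC, -0.03 in NK and -0.36 in T4 (adjusted p = 0.0557). No list differed between cell types (lowest adjusted p = 0.557).

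**Figure D4:**
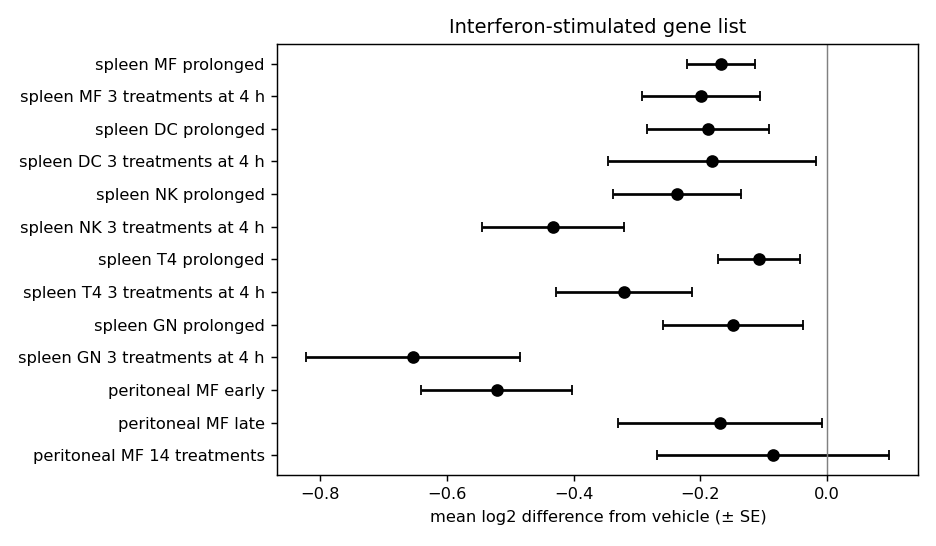
Mean log2 difference of the interferon-stimulated list from vehicle on the horizontal axis (points, with bars of 1 standard error) for each contrast of pooled inhibitors on the vertical axis. The early peritoneal contrast stood at -0.52 and the prolonged spleen contrasts between -0.24 and -0.11.

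Compounds were set side by side to ask whether they act on the same genes. In spleen MF the interferon-stimulated list was at -0.30 with SB00526221 (12 of 33 members lower adjusted over the list alone, 3 over all genes), -0.18 with SB00526222 and -0.02 with SB00526226. SB00526226 lay above SB00526221 by 0.29 in MF (95% confidence interval 0.104 to 0.471, adjusted p = 0.413) and by 0.43 in T4 (0.192 to 0.663, adjusted p = 0.203), which did not pass over the lists. In NK the same difference was 0.13 (-0.0776 to 0.335, adjusted p = 0.973). Prolonged T4 arrays of SB00526226 came from J8 only. SB00526222 minus SB00526221 was 0.13 in MF (-0.0423 to 0.295), 0.13 in DC (-0.248 to 0.498), 0.08 in NK (-0.138 to 0.307) and 0.08 in T4 (-0.11 to 0.279), and SB00513404 minus SB00526222 was -0.10 in early peritoneal MF (-0.455 to 0.249). Doses are not in the labels, so equal doses are not assumed. In NK cells, Cmklr1 and Ly6a2 were lower with SB00526228 than with SB00526222, by changes of -1.201 (SE 0.18) and -1.51 (SE 0.22). Both had adjusted p = 0.00331 by limma and lay lower in 3 of 3 arrays. J2 held all prolonged NK arrays of SB00526228 but only 1 of SB00526222, so 3 of 3 was counted against that 1 array. Of 56 splits of the arrays, 3 called as many genes, the real one included. Single compounds against vehicle gave 0 genes by limma in prolonged NK with SB00526221 (528 at an unadjusted p under 0.05), SB00526222 (235) and SB00526226 (379), and in prolonged T4 with SB00513404 (314), SB00526221 (249), SB00526222 (217) and SB00526226 (1181). In early peritoneal MF the same held for SB00526221 (236) and SB00526222 (580), and late for SB00513404 (934) and SB00526222 (72). Every other pair of compounds gave 0 genes by limma, with 105 to 1024 genes at an unadjusted p under 0.05. Fold changes of SB00526221 and SB00526222 correlated across genes at 0.433 in MF, 0.0454 in DC, 0.523 in NK and 0.371 in T4. Unchanged groups that share the vehicle arrays gave means of 0.32, 0.127, 0.602 and 0.362 in simulation. The central 95% of draws ran from -0.47 to 0.813 in MF and from -0.632 to 0.817 in DC. It ran from -0.139 to 0.926 in NK and from -0.368 to 0.846 in T4. The observed values lay within these ranges, so a shared action was not shown. With the vehicle arrays split between the compounds, the correlation averaged -0.057 in MF, -0.272 in DC and -0.299 in T4. These are correlations across genes, which are not independent replicates.

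The 2 vehicles were compared to ask whether acid in the vehicle shifts transcripts by itself. The limma test called 0 genes in spleen MF (194 at an unadjusted p under 0.05) and 0 in T4 (413), with 3 pH 3 arrays each. The kinase genes themselves (Jak1, Jak2 and Tyk2) did not pass in any contrast of pooled inhibitors against vehicle.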

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

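The tests of the clock genes below were chosen after the result was seen, and the screen for samples far from their group and for differences between schedules was planned. The schedules differed in 9 genes in spleen MF, 97 in NK and 1 in T4, each by a test of the difference itself. In NK cells the STAT5 target list (-0.45), the glucocorticoid-induced list (0.45) and a B cell marker list of 3 tested members (-0.37, adjusted p = 0.0369 by fry and adjusted p = 0.176 with an estimated correlation, 0 members past the threshold over all genes and 2 adjusted over the list alone) also passed between schedules by fry, but none of the 3 passed in J2 alone. Treatments and hours after the last treatment changed together and the 4 h arrays all came from J2, so the design did not separate an effect of the number of doses from one of the hours.

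The clock genes Nr1d1 and Nr1d2 stood out in arrays labelled spleen MF, where Nr1d1 lay between 9.39 and 10.64 in the 4 arrays taken at 4 h and between 7.25 and 9.385 in the 29 prolonged arrays. A rise within 6 h of 1 inhibitor treatment is argued against for peritoneal MF, where Nr1d1 was at 0.22 (SE 0.21). Of those 12 inhibitor arrays 7 had SB00513404, which no spleen MF array at 4 h had. Compound and number of treatments both differed, so these arrays do not decide on an inhibitor effect in spleen MF. The hour of harvest stays open: vehicle arrays of peritoneal MF differed by 1.30 between 6 h (10.3, n = 1) and 3 h (9.01 ± 0.26, SD, n = 5), and 1 array does not decide it. In the other cells of the spleen Nr1d1 was at -0.03 in DC, 0.24 in NK, -0.17 in T4 and 0.27 in GN at 4 h, and none passed. The difference may reflect the time of day in macrophages alone or 3 treatments in a row, and neither was tested directly.

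Single arrays lay far from their group for the interferon-stimulated list in 3 of 19 groups, where chance flags about 1 in 20 groups. Vehicle replicate 1 of early peritoneal MF, from J12, stood at 9.865 (gap over range 0.726) against a mean of 8.94 for the other 5, and leaving it out took the early count from 10 to 2 genes while the list stayed past the threshold. SB00526222 prolonged replicate 3 of DC, from J3, stood at 8.711 (0.844) against 9.175 for the others, and SB00513404 prolonged replicate 2 of T4, from J25, at 8.43 (0.835), below the others. The DC array also had a low median correlation with the other DC arrays (0.9703 against a median of 0.9868). No explanation of the 3 arrays was tested further.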

How the results depend on the processing

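The settings that leave out the arrays standing apart or keep some experiments alone, and the omission of single arrays for contrasts between schedules, were chosen after the results were seen, and the others were planned. The fall of interferon-stimulated genes in early peritoneal MF kept its direction and stayed past the threshold as a list under each setting run. No paired analysis was possible because the groups compared within a cell type came from different mice and replicate numbers follow only the order of the deposited arrays. Unless the fewer arrays or genes tested explain a value, the cause was not tested. Signal over background limits dim genes: those below the median of their array in all but a few arrays of a cell type were not tested.

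Dropping the experiment term changed 21 of 80 leading results. Counts became 301 in spleen MF at 4 h, 0 in MF prolonged, 30 in MF at 4 h against prolonged, 4 in NK at 4 h, 892 in NK at 4 h against prolonged, 3 in T4 at 4 h, 713 in T4 at 4 h against prolonged, 119 in GN at 4 h, 2 in GN at 4 h against prolonged and 0 in GN prolonged. Compound counts became 3 for SB00526221 and 0 for SB00526222 in MF, 0 for SB00526221 in DC, 0 for SB00526222 in GN, 4 for SB00513404 in early peritoneal MF and 15 for SB00526228 against SB00526222 in NK. Interferon list means passed at -0.28 in MF, -0.39 in NK and -0.38 in T4 at 4 h and at -0.30 in T4 at 4 h against prolonged, and the correlation of the compounds in NK was 0.855. Here the 4 h arrays, all of J2, are compared with other experiments without allowance for them.

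The experiment as a random block changed 16 results. Counts became 224 in NK at 4 h against prolonged, 19 in GN at 4 h, 1 in GN at 4 h against prolonged, 0 in GN prolonged, 0 in T4 at 4 h and 0 in T4 at 4 h against prolonged. Compound counts became 4 for SB00513404 in early peritoneal MF, 3 for SB00526221 and 0 for SB00526222 in MF, 0 for SB00526221 in DC and 0 for SB00526222 in GN. Between compounds 2 pairs passed, with 2 genes for SB00526226 and 5 for SB00526228 against SB00526222 in NK. List means passed at -0.41 in NK and -0.34 in T4 at 4 h.

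Quantile normalization changed 9 results, with counts of 0 in GN at 4 h, 15 in MF and 146 in NK at 4 h against prolonged, 1 for SB00526221 in MF and 9 for SB00513404 in early peritoneal MF. List means passed at -0.24 in MF, -0.42 in NK and -0.33 in T4 at 4 h and at -0.24 in T4 at 4 h against prolonged. Without the expression filter more genes were tested, with 2 genes for SB00526221 in DC and 0 in GN at 4 h. With camera the T4 mean at 4 h of -0.32 passed.

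Array quality weights changed 34 results. The weights ran from 0.104 to 4.96 in spleen MF and from 0.19 to 6.62 in peritoneal MF, and their estimation stopped short of its tolerance in at least 1 fit. Counts were 81 in MF prolonged, 110 in MF at 4 h, 375 in MF at 4 h against prolonged, 4 in DC at 4 h, 111 in NK prolonged, 368 in NK at 4 h, 954 in NK at 4 h against prolonged, 19 in T4 at 4 h, 20 in T4 at 4 h against prolonged, 7 in GN prolonged, 31 in early and 1068 in late peritoneal MF. Compound counts were 157 for SB00526221 in MF, 53 for SB00526221 in DC, 21, 212 and 548 for SB00526222, SB00526226 and SB00526228 in NK, 204 for SB00513404 in T4, 46 for SB00526222 in GN, 25 early and 3872 late for SB00513404 and 2241 early for SB00526222 in peritoneal MF. Between compounds they were 11 and 19 in MF (SB00526222 and SB00526226 against SB00526221), 11 and 363 in NK (SB00526226 and SB00526228 against SB00526222), and 4957 early and 1966 late in peritoneal MF (SB00513404 against SB00526222). The pH 3 vehicle gave 1 gene in T4, 1 cell type past the threshold in all, the cell types differed in 7 genes, 26 compound contrasts and 6 pairs had called genes, and the NK list at 4 h passed at -0.34.

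With both vehicles as 1 control the counts were 83 in MF prolonged, 92 for SB00526221 in MF, 3 in T4 at 4 h, 8 in GN prolonged and 16 for SB00526222 in GN. In J2 alone, with fewer arrays, they were 0 and 3 in MF, 8 and 3 in DC, and 24 and 18 in NK for 4 h against vehicle and against prolonged, 2 in T4 at 4 h against prolonged and 1 in GN at 4 h. Without the arrays standing apart they were 18 in MF at 4 h against prolonged, 3 in DC at 4 h, 132 in NK at 4 h, 162 in NK at 4 h against prolonged, 35 for SB00526221 and 0 for SB00526222 in MF, 4 for SB00526221 in DC and 8 for SB00526228 in NK, and 3 pairs of compounds passed, with 1 and 4 genes for SB00526222 and SB00526226 against SB00526221 in MF. Arrays at 3 h alone gave 32 genes in early peritoneal MF and 6 for SB00513404. T4 of J2 and J25 alone gave 2 genes. No leading result changed without arrays of 28 treatments, with vehicle of 14 treatments alone, with the pH 3 vehicle for SB00526226, with only experiments holding both arms, or in T4 of J3, J6 and J8 alone.

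Of 35 named genes past the threshold, 15 were lost without the experiment term, 8 with the random block, 11 without the filter, 5 after quantile normalization and 1 without the arrays standing apart, and in J2 alone 13 of 21. Of 4 other lists past the threshold, 4 were lost in J2 alone, 3 without the filter, 3 with camera, 1 without the experiment term, 1 with the random block and 0 after quantile normalization, and in 43 of 71 fits that left out 1 array. Each array was also left out in turn, and the number of genes called is given for each contrast it changed. For spleen MF prolonged the number ran from 1 to 41 (1 with all arrays), with 2 without vehicle replicate 1, SB00526226 prolonged replicate 1, SB00526221 prolonged replicate 5, SB00526222 prolonged replicate 6, 3 without SB00526226 prolonged replicate 3, 10 without SB00526222 prolonged replicate 4 and 41 without vehicle replicate 7. For spleen MF SB00526221 prolonged the number ran from 1 to 66 (18 with all arrays), with 1 without vehicle replicate 4, 5 or 8, SB00526221 prolonged replicate 4 or 6, 2 without vehicle replicate 1, 3 without SB00526221 prolonged replicate 3, 5 without SB00526221 prolonged replicate 2 or 5, 10 without vehicle replicate 2, 42 without SB00526221 prolonged replicate 1 and 66 without vehicle replicate 7. For spleen MF at 4 h against prolonged the number ran from 0 to 39 (9 with all arrays), with 0 without SB00526221 at 4 h replicate 1, 3 without SB00526222 at 4 h replicate 2, 4 without SB00526222 prolonged replicate 1, 5 without SB00526221 prolonged replicate 5, SB00526222 prolonged replicate 6 or 7, SB00526226 prolonged replicate 4, 18 without SB00526221 prolonged replicate 1, SB00526222 prolonged replicate 5 and 39 without SB00526226 at 4 h replicate 1. For spleen MF at 4 h the number ran from 0 to 3 (2 with all arrays), with 0 without SB00526221 at 4 h replicate 1 and 1 without SB00526222 at 4 h replicate 2. For spleen MF SB00526222 prolonged the number ran from 0 to 1 (1 with all arrays), with 0 without SB00526222 prolonged replicate 1, 3, 5, 6 or 7, vehicle replicate 3, 6, 7 or 8. For spleen DC SB00526221 prolonged the number ran from 0 to 3 (1 with all arrays), with 0 without vehicle replicate 1, 3 or 5, SB00526221 prolonged replicate 1, 3 or 5, 2 without vehicle replicate 2 and 3 without vehicle replicate 6. For spleen NK at 4 h the number ran from 1 to 16 (13 with all arrays), with 1 without vehicle replicate 1, 2 without SB00526226 at 4 h replicate 1, 3 without SB00526221 at 4 h replicate 2, 6 without SB00526221 at 4 h replicate 1, SB00526226 at 4 h replicate 2 and 7 without vehicle replicate 2. For spleen NK SB00526228 prolonged the number ran from 1 to 6 (5 with all arrays), with 1 without vehicle replicate 1 and 3 without SB00526228 prolonged replicate 2. For spleen NK at 4 h against prolonged the number ran from 37 to 160 (97 with all arrays), with 37 without SB00526226 prolonged replicate 1, 39 without SB00526221 prolonged replicate 2, 41 without SB00526221 at 4 h replicate 2, 46 without SB00526222 prolonged replicate 1, 49 without SB00526226 at 4 h replicate 2, 58 without SB00526226 at 4 h replicate 1, 146 without SB00526221 prolonged replicate 6 and 160 without SB00526222 at 4 h replicate 1. For spleen T4 at 4 h the number ran from 0 to 3 (1 with all arrays), with 0 without vehicle replicate 1, 2 without vehicle replicate 2 and 3 without SB00526222 at 4 h replicate 1, SB00526226 at 4 h replicate 1. For spleen T4 at 4 h against prolonged the number ran from 1 to 7 (1 with all arrays), with 2 without SB00526222 at 4 h replicate 1, SB00526226 prolonged replicate 1, SB00526222 prolonged replicate 5, 4 without SB00526221 prolonged replicate 4 and 7 without SB00526226 at 4 h replicate 1. For spleen T4 SB00526226 prolonged the number ran from 0 to 9 (0 with all arrays), with 1 without vehicle replicate 7 and 9 without SB00526226 prolonged replicate 3. For spleen GN at 4 h the number ran from 0 to 7 (5 with all arrays), with 0 without SB00526221 at 4 h replicate 1, SB00526222 at 4 h replicate 2, vehicle replicate 3, 1 without vehicle replicate 4 and 2 without SB00526222 at 4 h replicate 1. For spleen GN prolonged the number ran from 0 to 8 (3 with all arrays), with 0 without SB00526222 prolonged replicate 1 or 3 and 8 without vehicle replicate 3. For spleen GN SB00526222 prolonged the number ran from 3 to 13 (5 with all arrays), with 3 without SB00526222 prolonged replicate 1, 9 without vehicle replicate 5, 10 without vehicle replicate 4 and 13 without vehicle replicate 3. For spleen GN at 4 h against prolonged the number ran from 0 to 1 (0 with all arrays), with 1 without SB00526222 prolonged replicate 3. For peritoneal MF early the number ran from 2 to 26 (10 with all arrays), with 2 without vehicle replicate 1, 2 or 5, 4 without SB00526221 replicate 1 or 2, SB00513404 replicate 1 or 6, 5 without SB00513404 replicate 2, 6 without SB00526222 replicate 2 and 26 without vehicle replicate 4. For peritoneal MF SB00513404 early the number ran from 1 to 7 (2 with all arrays), with 1 without SB00513404 replicate 1 or 2, 4 without SB00513404 replicate 3 or 7, vehicle replicate 6 and 7 without vehicle replicate 4.

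The interferon list of spleen MF at 4 h against prolonged, at -0.01 with all arrays, ran from -0.0462 to 0.0388 and turned without SB00526222 prolonged replicate 1 (0.003833), SB00526221 prolonged replicate 5 (0.001218), SB00526226 prolonged replicate 2 (0.03876) and SB00526222 at 4 h replicate 2 (0.02055), so its direction is not determined.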

Other observations

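The tests of macrophage identity and of the T4 groups below were chosen after the results were seen, and the splits of arrays and the gene lists were planned. Groups of 1 array have no spread of their own and were tested with that of the other groups. In granulocytes such tests of SB00526221 called 10 genes at 4 h and 16 after prolonged treatment, which are not described further. SB00526222 called 5 lower genes on 2 arrays at 4 h and 5 higher genes on 3 prolonged arrays. In NK cells at 4 h, SB00526226 and SB00526221 each called 7 genes, on 2 arrays each. With SB00526226, F2rl2, a thrombin receptor cofactor, was at -2.10 and Klrb1a, an NK receptor, at -1.35. With SB00526221, Ccl3, an inflammatory chemokine, was at +0.92. All these 4 h groups were set against vehicle of the prolonged schedule, so hour and number of treatments were not separated from inhibitor. SB00513404 lowered Rtp4 (-1.82) and Xaf1 (-0.93) in early peritoneal MF, its 2 called genes, with 442 at an unadjusted p under 0.05. A single T4 array 3 h after 1 treatment with SB00513404 had the interferon-stimulated list at -0.48 against 1 vehicle array. At 18 h after 1 treatment the list was at -0.28 with SB00513404 (2 arrays) and -0.13 with SB00526222 (1 array). Those 18 h groups were set against the prolonged vehicle, so number of treatments and inhibitor were not separated. These compound results carry the names chosen after their values were seen where they lie outside the rule.

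Arrays labelled spleen MF carried the profile of peritoneal macrophages: their peritoneal macrophage marker list averaged 12.08 ± 0.14 (SD, n = 33) against 11.99 ± 0.13 in peritoneal MF and 6.73 in DC, a difference of 0.09143. Red pulp macrophages as the main cell are argued against, since the mean of Spic, Vcam1 and Slc40a1 lay at -0.58 relative to T4 cells. The full splenic macrophage marker list was higher in spleen MF (9.949) than in T4 (6.617). It was as high in peritoneal MF (9.998), so it does not tell splenic from peritoneal macrophages. Normalization across all arrays is argued against too, since no other spleen cell type correlated with peritoneal MF above 0.9055 while spleen MF reached 0.9971. Peritoneal macrophages in arrays with a spleen tissue label may therefore be the source, through the label or the collection, and the labels cannot separate these.

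T4 arrays of J3, J6 and J8 (16 arrays) stood apart from those of J2 and J25 (23 arrays), a grouping found from the data. Klrb1c, which encodes NK1.1, averaged 9.58 against 5.41, with Cxcr3 higher by 2.81, Zbtb16 by 2.02 and Cd44 by 1.16. NK cells among the sorted cells are argued against: at the share of 16.7% that Klrb1c would need, the median of 8 other NK markers would rise by 4.11, and it rose by 0.32. The inhibitors are argued against by vehicle arrays alone, where Klrb1c differed by 3.96. More memory-type or NKT-like cells among the CD4+ cells may explain it, since Ccr7, a receptor of naive cells, lay at -1.20, and a different sort gate in those experiments stays open.

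Other splits of the same arrays into groups of the same sizes were fitted for each contrast with at least 3 arrays per group, 100 drawn where there were more. Arrays were exchanged across experiments, whereas the real 4 h arrays all came from J2. Splits of the 4 h contrasts therefore had another layout over experiments than the real grouping, which limits what they show. Each contrast was judged alone, without allowance for the number of contrasts. Judged so, only the real grouping reached the count for NK at 4 h (13 genes, 1 of 100 splits, highest other 1). The same held for SB00513404 in early peritoneal MF (2 genes, 1 of 100, highest other 1). A share of 1 in 100 is the smallest that 100 splits can give, and both counts fell to 1 in a fit that left out 1 array. Less than 5 of 100 splits gave as many genes for SB00526221 in spleen MF (18, 2 of 100, highest other 145) and DC (1, 2 of 100, highest other 1), for SB00526222 in spleen MF (1, 3 of 100, highest other 10), and for 4 h against prolonged in NK (97, 4 of 100, highest other 2194) and MF (9, 4 of 100, highest other 1187). Chance is left open for all of these contrasts, since so many were tried and most of these counts fell to 0 or 1 without a single array. Chance cannot be excluded for the pooled early peritoneal count (10, 5 of 100, highest other 2388), for MF prolonged (1, 6 of 100, highest other 3302) and at 4 h (2, 10 of 100, highest other 1302), for T4 at 4 h (1, 14 of 100, highest other 1224) and against prolonged (1, 11 of 100, highest other 2962), or for GN prolonged (3, 5 of 100, highest other 23) and at 4 h (5, 8 of 100, highest other 113). Nor can it for SB00526222 in GN (5, 5 of 55, highest other 328) or SB00526228 against SB00526222 in NK (2, 3 of 56, highest other 36). For SB00526228 against vehicle in NK the 10 splits are too few for a share under 0.05 (5 genes, highest other 4, 1 split as large).

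The contrasts with 0 genes were matched by every split, since no split gives fewer. In 100 of 100 the highest other count was 2 for SB00526226 in MF, 1576 in DC prolonged, 1669 for SB00526222 in DC, 1318 in NK prolonged, 1890 for SB00526221 in NK, 498 in T4 prolonged, 0, 9, 402 and 1641 for SB00513404, SB00526221, SB00526222 and SB00526226 in T4, 3 in GN at 4 h against prolonged, 1110, 139 and 822 in peritoneal MF late, after 14 treatments and early against late, and 632 between cell types. Between compounds, also in 100 of 100, it was 85, 4627 and 1 in MF, 1 in DC, 346, 1 and 473 in NK, 355 and 0 in T4 and 1225 in early peritoneal MF, and between vehicles 0 in MF and 677 in T4. With fewer splits it was 3 for SB00526222 (56 of 56) and 1 for SB00526226 (35 of 35) in NK, and 3710 for SB00526222 early (84 of 84). Late peritoneal MF gave 2203 for SB00513404, 4 for SB00526222 and 1626 between them (35 of 35 each), and in T4 SB00526226 gave 3557 against SB00526222 (84 of 84) and 521 against SB00526221 (56 of 56). Some splits called many more genes than the real grouping, and the reason was not tested.

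Over the contrasts of pooled inhibitors against vehicle, 13 for most lists, each list fixed in advance is given by its lowest adjusted p by fry and its mean there. Only the interferon-stimulated list (-0.52, adjusted p = 0.00747, early peritoneal MF) and the splenic macrophage marker list (0.92, 0.0263, DC at 4 h) passed. The adjustment covered more tests in the spleen contrasts than in the peritoneal ones, so these adjusted p-values are not on equal terms. In spleen MF at 4 h these were the circadian clock list (0.36, 0.0719), the platelet and megakaryocyte markers (-0.28, 0.117), the NK effector list (0.25, 0.329) and the B cell markers (-0.56, 0.329). DC at 4 h gave the immediate early list (0.52, 0.117), the glucocorticoid-induced list (0.26, 0.194), the plasmacytoid dendritic cell markers (0.59, 0.505) and the JAK-STAT component list (0.23, 0.545). NK cells at 4 h gave the cell cycle list (-0.46, 0.3), the cholesterol synthesis list (-0.19, 0.3), MHC class I (0.25, 0.3), STAT5 targets (-0.26, 0.3), mast cell and basophil markers (0.20, 0.347) and the T cell activation list (-0.25, 0.407). Prolonged NK gave the monocyte markers (-0.31, 0.335) and the NF-kB list (0.18, 0.379). T4 at 4 h gave the heat shock list (0.26, 0.195), the T cell markers (0.16, 0.407) and the NK cell markers (-0.37, 0.477). Granulocytes at 4 h gave the conventional dendritic cell markers (-0.27, 0.388) and STAT3 targets (0.33, 0.514), and prolonged granulocytes the neutrophil markers (0.42, 0.335), STAT6 targets (0.58, 0.379), MHC class II (0.35, 0.423) and erythroid markers (-0.17, 0.708). Peritoneal MF gave the interferon-gamma list (-0.20, 0.185, early) and the peritoneal macrophage markers (0.17, 0.414, after 14 treatments).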
